A study of Salmo salar with 16 samples.

How the data were processed

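Liver RNA of 16 juvenile Atlantic salmon, 4 from each of 4 groups, was labelled with the dye Cy3 and hybridised to 16 one-colour Agilent oligonucleotide arrays, 1 array per fish, per the labels' protocols. Each array held 62976 spots, of which 61657 were not control spots and carried 55468 probes. Of these probes 49679 were printed on 1 spot, 5739 on 2 spots and 50 on 10 spots.

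The deposited scanner files give each spot's brightness as a linear intensity with no normalization between arrays. The processed signal intensity had been background-subtracted and corrected for spatial trend within the array by Agilent Feature Extraction 10.7, per the file headers and the submitters' processing notes. The deposited flags, which mark outlier spots, saturation and signals well above background and are coded as 1 or 0, were also set by that program, per the file headers. The deposited value table of the authors holds log2 values for 45366 probes. How it was made is not given in the sources used here, so it was set against the scanner files. Each probe's median over its 16 columns was 0 within rounding, and the column medians lay between -0.02 and 0.02. It differed from quantile-normalized log2 scanner values, centred on each probe's median, by a median of 0.000812 log2, against 0.0547 for values scaled by the 75th percentile. Differences between columns followed those between scanner files with a slope of 0.998 among the brightest probes, so that scale, centring and direction were settled by this comparison. For 14 of the 16 columns, however, the matching scanner file carried another replicate number of the same group. Replicate numbers below are those of the scanner files.

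For the main analysis, log2 of the processed signal was taken, spots with an outlier flag were left out (417 spots over all arrays, none saturated), spots of 1 probe were averaged, and the 75th percentile of each array was subtracted. A probe was tested if it was well above background on at least 4 of the 16 arrays and had a value on every array, which left 37242 probes. Another 121 probes lacked a value on some array. Group means were fitted to all 16 arrays at once with limma 3.58.1 in R 4.3.3 (12 residual degrees of freedom), followed by empirical Bayes moderation and Benjamini-Hochberg adjustment over all tested probes of a comparison, with a threshold of 0.05. The 6 comparisons were Gamma, DU and Combi against Control, Combi against Gamma, Combi against DU, and the interaction, (Combi minus Gamma) minus (DU minus Control). These comparisons, the main model and most alternatives were fixed before the data were examined.

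The files name each probe by a custom probe name and a contig ID and do not pair either with genes. None (0) of the 55418 distinct contig IDs, with or without prefix and suffix, matched an identifier among the 65341 genes of the RefSeq table for assembly Ssal_v3.1, and neither did a probe name. The rule fixed beforehand named only probes with a gene name, by largest change among probes past the threshold or otherwise by smallest p, together with classical radiation, metal and oxidative stress genes. That rule, the gene lists and the cell type markers therefore could not be applied, and no gene is named. For the same reason at most 2 contig IDs are printed in each direction, those of smallest p over the comparisons with Control, chosen after the values had been seen. By the form of their contig ID, 35676 probes had digits only, 16491 started with OM_UG, 2992 started with SS_UG and 309 ended in _AS.

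The arrays lay on 2 slides of 8, with 2 arrays of every group on each slide. The slides were scanned at 2 times on 1 day, so slide and scan were the same split. The slide was tested as a block and each comparison was also fitted within each slide. Whether equal replicate numbers marked paired fish was checked by the correlation, across probes, of deviations from the group means. Of the 24 pairs of equally numbered arrays in different groups, 10 had a correlation above 0.1, with a range from -0.36 to 0.33, so the numbers were not taken to pair the fish. The labels do not say whether the fish of a group shared a tank, so p-values measure the spread between these fish only.

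Alternatives were normexp background correction (offset 50), quantile normalization, centring on the median, the authors' value table, other filters on dim probes, outlier spots kept, an intensity trend in the moderation, array weights, fits restricted to the groups compared, the replicate number or slide as a block, contig averages, other thresholds and leaving out each array in turn. The mean spot signal was not among the columns, so normexp used the median spot signal and the median local background. The fit was tested on simulated data in which 200 probes of 1 group were changed by known folds. The residuals of the real arrays were shuffled for this without regard to slide. Counts at an unadjusted p under 0.05, effects averaged over the other factor, and tests of probe classes were added after the data had been seen. The number of arrays limits the precision.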

Results

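Liver transcript levels were measured in juvenile Atlantic salmon (parr) after 48 h in a 2-by-2 design of external gamma radiation and waterborne depleted uranium. The fish were acclimated to lake water for 72 h and were not fed. The 4 groups of 4 fish each were untreated fish (Control), fish given 70 mGy from a cobalt-60 source during the first 5 h (Gamma), fish kept in 0.25 mg/L depleted uranium (DU), and fish given both (Combi). Depleted uranium is uranium with a lowered share of its fissile isotope, and is a toxic heavy metal as well as a weak emitter of alpha particles. Each fish was measured on its own array. Between 56.8% and 66.7% of probes were well above background on an array. The 75th percentile of the processed signal lay between 110 and 197 in Control, 118 and 218 in Gamma, 114 and 150 in DU, and 122 and 184 in Combi, so the DU arrays were dimmer than most others before scaling. All levels below are log2 signal after subtraction of each array's 75th percentile.

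Slide separated the arrays more than treatment did along the main component of variation. The first principal component of the 37242 tested probes held 19.6% of the variance, and slide accounted for 57.1% of the spread along it against 7.61% for the 4 groups. On the smaller components 2, 3, 4 and 6 the groups accounted for 25.4%, 24.1%, 44.2% and 31.8%, and the slide for 20.0%, 2.56%, 8.08% and 0.0378%. By chance alone, 4 groups account for more of any component than 2 slides do. The larger group shares therefore do not show that treatment outweighed slide on these components. Between slides, 2662 probes differed at an adjusted p under 0.05 in limma, 480 higher and 2182 lower on the second slide, and 996 of these differed at least 2-fold. Every group had 2 arrays on each slide, so this difference added to the spread within groups without shifting the group means against each other. The median standard deviation of a probe among the 4 fish of a group was 0.31 log2 in Control, 0.39 in Gamma, 0.34 in DU and 0.34 in Combi. Among fish of 1 group on 1 slide it was 0.28, 0.30, 0.31 and 0.31. The within-slide values rest on fewer degrees of freedom, which alone lowers their median, so the fall need not all be due to the slide.

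**Figure D1:**
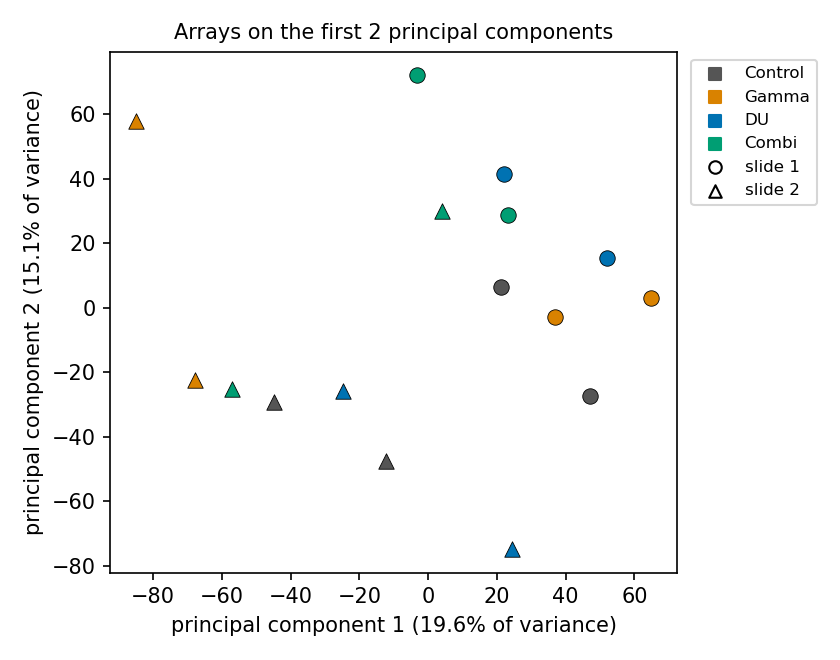
Scores of the 16 arrays on principal components 1 and 2 of log2 signal, coloured by group, with circles for slide 1 and triangles for slide 2. Slide accounted for 57.1% of the spread along component 1, and the 4 groups overlapped.

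No comparison yielded a probe that passed the test. In all 6 comparisons 0 of 37242 probes reached an adjusted p under 0.05 in limma, with and without the slide as a block, and also when each slide was fitted alone. No tool other than limma was run. Counts at an unadjusted p under 0.05 are given below as a description of the distributions, beside the 1862 probes that chance alone would give. They are not calls. The share of higher probes among them stayed below 50% in all 32 alternatives only for Gamma against Control (37.1% to 49.5%). In the other 5 comparisons the majority turned in some alternatives. The share ranged from 36.4% to 76.6% for DU against Control, 42.3% to 51.7% for Combi against Control and 39.3% to 56.9% for Combi against Gamma. It ranged from 34.4% to 52.9% for Combi against DU and from 40.9% to 68.4% for the interaction.

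**Figure D2:**
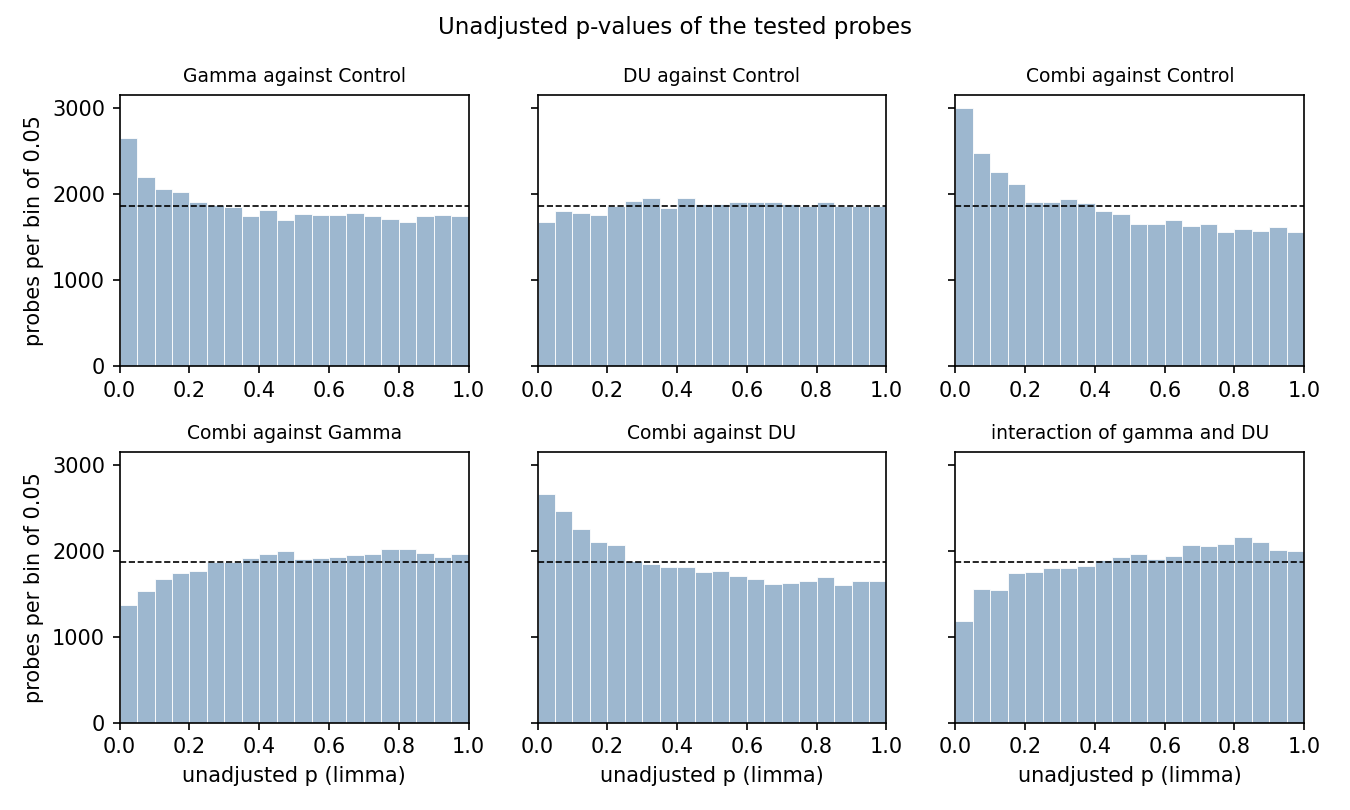
Number of tested probes in each 0.05-wide bin of unadjusted limma p, for the 6 comparisons. The dashed line marks 1862 probes, the number per bin with no effect. The lowest bin holds 3001 probes for Combi against Control and 1182 for the interaction.

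Gamma radiation alone was compared with Control to ask whether 70 mGy changed liver transcripts. No probe passed, and the smallest adjusted p was 0.25 (limma). At an unadjusted p under 0.05 there were 2653 probes, 1107 higher and 1546 lower in Gamma, of which 579 and 992 differed at least 1.5-fold. The probe of contig 5615428 had the smallest p among those lower in a treated group. Its level was -2.49 ± 0.55 (SD, n = 4) in Control and -4.45 ± 0.27 (n = 4) in Gamma, a log2 difference of -1.96 with a standard error of 0.32 and an adjusted limma p of 0.25. It was well above background on 4 Control arrays but on only 1 of 4 Gamma arrays and 1 of 4 DU arrays. Its Gamma level therefore lay near the detection limit and the size of the difference is not settled. After normexp background correction the difference was -0.54, but the added offset alone shrinks log2 differences of dim probes. The probe of contig 5698086 was at 0.67 ± 0.06 (SD, n = 4) in Control and -0.15 ± 0.10 (n = 4) in Gamma, a log2 difference of -0.83 ± 0.14 (SE) with an adjusted limma p of 0.25. Its difference from Control was -0.76 in Combi and -0.38 in DU, and all 4 Gamma arrays lay below all 4 Control arrays. The 3 differences share the 4 Control arrays and the probe was picked by 1 of them, so they are not separate observations. The Gamma and Control arrays did not overlap for 4.29% of probes, against 2.86% by chance. With the slide as a block the unadjusted count was 3027. It was 3071 on slide 1 and 2680 on slide 2, and the differences on the 2 slides were uncorrelated across probes (r = -0.00538), which are not independent replicates.

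Uranium alone was compared with Control to ask whether 0.25 mg/L changed liver transcripts. No probe passed, and the smallest adjusted p was 0.392 (limma). At an unadjusted p under 0.05 there were 1675 probes, fewer than chance would give, 754 higher and 921 lower in DU. Of these, 475 and 501 differed at least 1.5-fold. The probe of contig 5418591 was at -2.14 ± 0.29 (SD, n = 4) in Control and -0.61 ± 0.21 (n = 4) in DU, a log2 difference of 1.53 with a standard error of 0.28 and an adjusted limma p of 0.392. After normexp background correction the difference was 0.79, a fall that the added offset alone can produce in part in a dim probe. The level of this probe was -2.09 ± 0.40 in Gamma and -1.44 ± 0.60 in Combi. The probe of contig 5630556 was at 0.12 ± 0.19 in Control and 1.04 ± 0.05 in DU, a log2 difference of 0.92 ± 0.16 (SE) with the same adjusted limma p. It was also above Control in the other exposed groups, by 0.59 in Gamma and 0.86 in Combi. These differences share the 4 Control arrays with the one the probe was picked by, so they are not separate observations. Both probes were well above background on all 16 arrays, and for each all 4 DU arrays lay above all 4 Control arrays. Arrays of the 2 groups did not overlap for 3.09% of probes, against 2.86% by chance. The share of higher probes among the unadjusted count was 45.0%, and 55.2% after normexp background correction. With every probe tested, including dim ones, the unadjusted count was 4243, of which 76.6% were higher in the dimmer DU arrays, and 0 passed the adjusted threshold. With array weights it was 2647. A single probe passed when only the arrays of the 2 groups were fitted, and another when Control replicate 1 or Control replicate 3 was left out, a different one each time. With the slide as a block the unadjusted count was 2168, and it was 2247 on slide 1 and 1106 on slide 2 (r = 0.13 between the slides' differences, across probes).

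**Figure D3:**
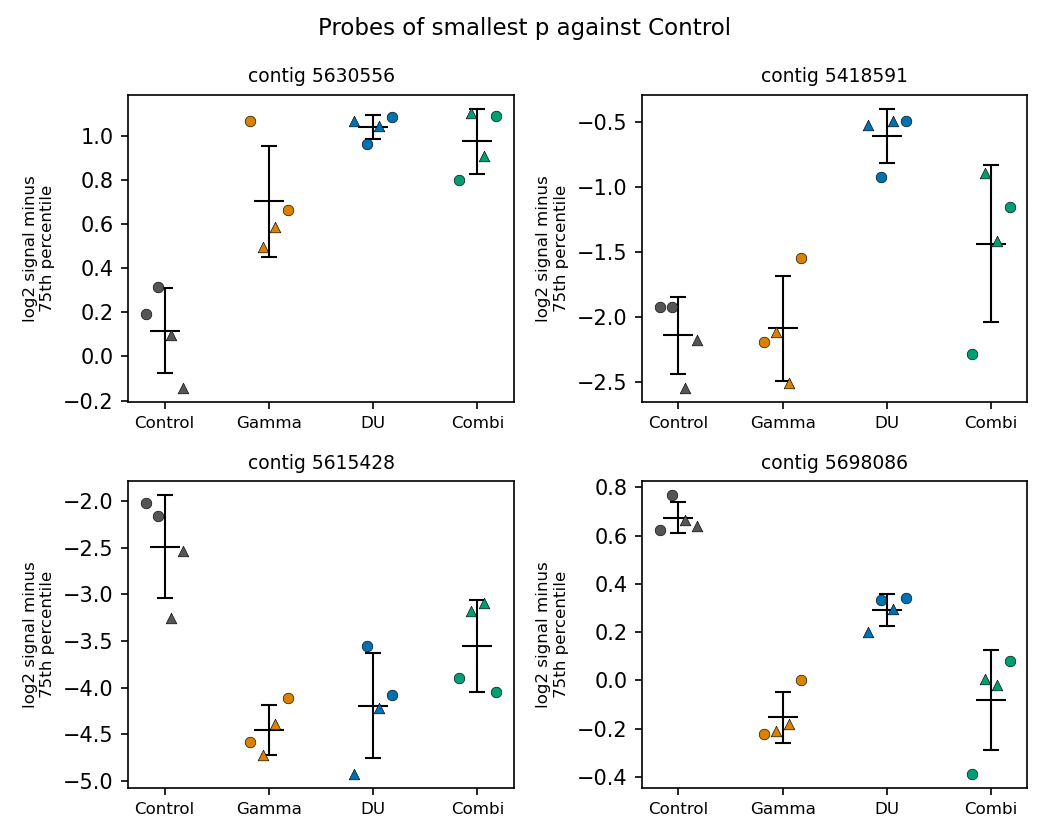
Log2 signal of 4 probes in each of the 16 fish (circles slide 1, triangles slide 2), with the mean and SD of each group of 4. Contig 5630556 has its lowest mean in Control, contig 5418591 its highest in DU, and contigs 5615428 and 5698086 their highest in Control. None passed the adjusted threshold against Control.

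The combined exposure was compared with Control to ask what both stressors did together. No probe passed, and the smallest adjusted p was 0.427 (limma). The unadjusted count was 3001 probes, 1409 higher and 1592 lower in Combi, of which 884 and 1000 differed at least 1.5-fold. Combi and Control arrays did not overlap for 6.06% of probes, 1153 higher and 1105 lower, against 2.86% by chance. With the slide as a block the unadjusted count was 3491, and it was 3179 on slide 1 and 1529 on slide 2 (r = 0.24 between the slides' differences, across probes). Without Control replicate 1, or without Control replicate 3, 1 probe passed, the same one as for DU against Control in each case.

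Combi was compared with Gamma to ask what uranium added in irradiated fish. No probe passed at 0.05, but 6 probes had an adjusted p between 0.0779 and 0.0819 in limma, and each of them was lower in Combi. Their log2 differences ran from -3.01 to -1.63. For 1 of the 6 no Combi array was well above background, so that its level there is only a bound, and the other 5 differed between 3.09-fold and 8.04-fold. In each of the 6 all 4 Gamma arrays lay above all 4 Combi arrays, the Gamma mean was the highest of the 4 groups and the Combi mean was the lowest. Combi was the lower group on both slides. The 6 probes were selected by this difference and varied together across the arrays, so they are not 6 separate observations. For the 5 measured in Combi, the Control mean lay between those of Gamma and Combi. Gamma minus Control ran from 0.50 to 0.97 and Combi minus Control from -2.04 to -1.13. Single Control fish did not keep this order. In the probe that differed most, Control levels ran from -0.52 to 1.94, beside 1.33 to 1.63 in Gamma. The 6 probes did pass the 0.05 threshold in some alternative fits. Of them, 5 passed when only probes well above background on all 16 arrays were tested. The numbers passing at 0.05 ranged from 0 to 5 over the alternatives, with 4 when Control replicate 3 or Control replicate 4 was left out, and no probe passed with the slide as a block, where the smallest adjusted p was 0.0908. Arrays of the 2 groups did not overlap for 1.84% of all tested probes, 323 higher and 362 lower in Combi, against 2.86% by chance. Over all probes the unadjusted count was 1367, below the 1862 of chance, with 646 higher and 721 lower in Combi. This balance turned after normexp background correction (56.9% higher). The unadjusted count was 1655 with the slide as a block, 3160 on slide 1 and 2074 on slide 2 (r = -0.16, across probes). It was 2425 without Gamma replicate 2.

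**Figure D4:**
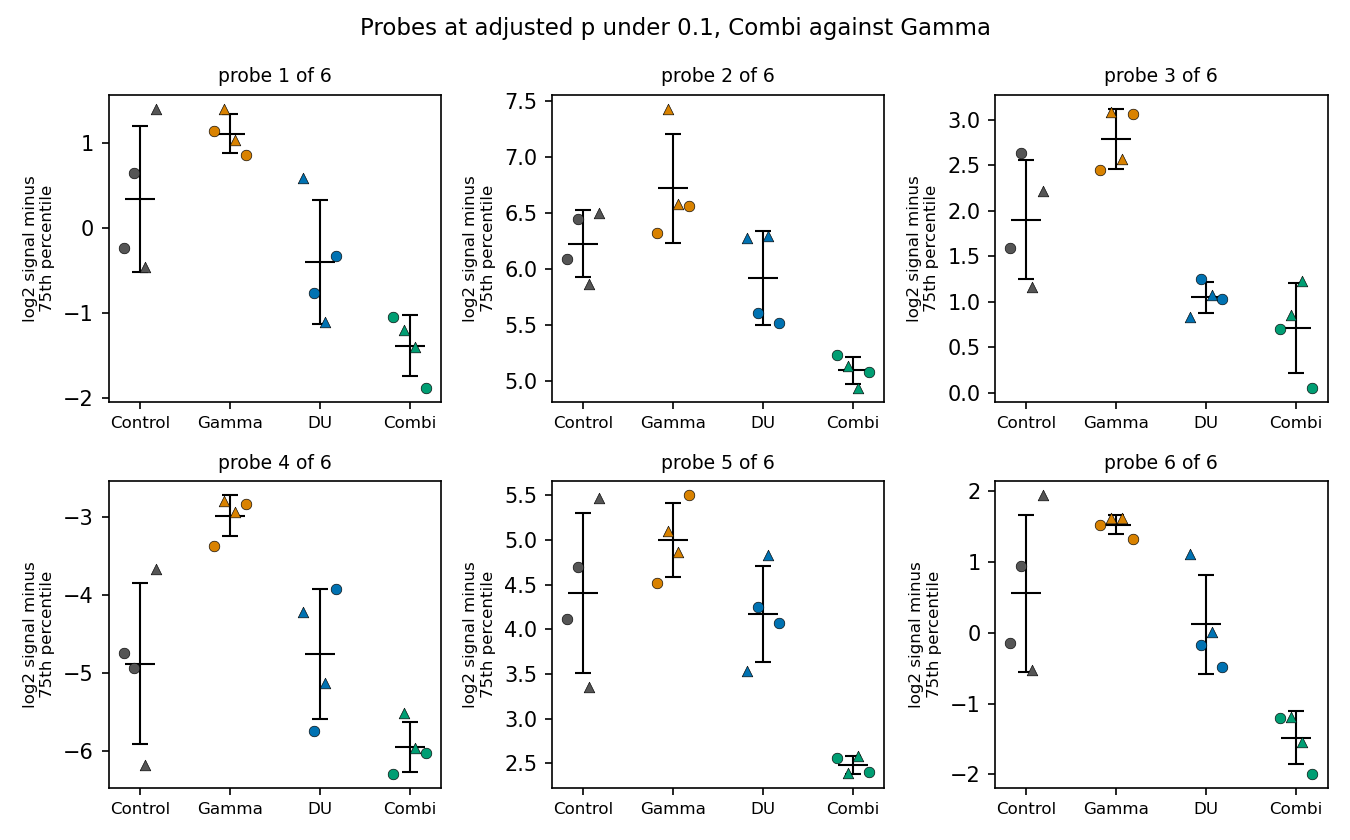
Log2 signal of the 6 probes with an adjusted p under 0.1 in Combi against Gamma, in each of the 16 fish (circles slide 1, triangles slide 2), with the mean and SD of each group of 4. In every panel the 4 Combi fish lie below the 4 Gamma fish, and none of the 6 passed the threshold of 0.05.

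Combi was compared with DU to ask what gamma radiation added in fish exposed to uranium. No probe passed, and the smallest adjusted p was 0.0713 (limma), of a probe with a log2 difference of -3.40 between Combi and DU. The unadjusted count was 2653, with 1201 probes higher and 1452 lower in Combi, of which 753 and 996 differed at least 1.5-fold. With percentiles taken over the tested probes alone, a setting added after the data had been seen, the share of higher probes was 34.4% in place of 45.3%, and it was 52.4% with arrays centred on the median of the tested probes. Arrays of the 2 groups did not overlap for 4.87% of probes, against 2.86% by chance. With the slide as a block the unadjusted count was 3321, and it was 1699 on slide 1 and 2139 on slide 2 (r = 0.25 between the slides' differences, across probes). Without Combi replicate 3 the unadjusted count was 1754. In some alternative fits 1 to 3 probes passed, 3 after normexp background correction and 1 when Gamma replicate 3 or DU replicate 2 was left out.

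The interaction asked whether the combined difference departed from the sum of the single differences. No probe passed, and the smallest adjusted p was 0.602 (limma). The unadjusted count was 1182, below the 1862 of chance, with 695 probes above and 487 below the sum. It was 773 after normexp background correction (68.4% above the sum, against 58.8%) and 1878 with every probe tested (40.9% above), and 0 passed in either. The median standard error of a probe's interaction was 0.38 log2, against 0.27 for a difference between 2 groups. Across probes, the slope of the combined difference on the sum of the single differences was 0.427. All 3 differences share the Control arrays, so a slope below 1 arises from chance alone and was not tested. With the slide as a block the unadjusted count was 1479, and it was 2008 on slide 1 and 1176 on slide 2 (r = -0.00313, across probes).

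The design holds each stressor's difference in pairs that share no array. The gamma difference without uranium (Gamma minus Control) and with uranium (Combi minus DU) had a Pearson correlation of 0.258 across probes and a Spearman correlation of 0.302. Of 100 assignments of gamma to arrays, the real one included, 9 gave a Pearson correlation as high (one-sided permutation p = 0.09, and 0.18 after Benjamini-Hochberg adjustment over the 2 relations). Among distinct assignments within slides it was 6 of 100, and in a first set of draws within slides, with repeats, 4 of 100, and the correlation was 0.0474 on slide 1 and 0.259 on slide 2. It was 0.123 without Gamma replicate 2, 0.144 without Control replicate 1 and 0.416 after normexp background correction. Of the 2653 probes at an unadjusted p under 0.05 in Gamma against Control, 73.9% had the same sign in Combi against DU, against 61.7% of all probes. The uranium difference without gamma (DU minus Control) and with gamma (Combi minus Gamma) had a correlation of 0.116 (Spearman 0.112), with 32 of 100 assignments as high (one-sided permutation p = 0.32, also 0.32 after adjustment). It was 0.171 on slide 1 and 0.126 on slide 2, and 0.252 after normexp background correction. It was 0.0136 without DU replicate 2, 0.0163 without Gamma replicate 3, 0.0662 without Control replicate 4, 0.0738 without Combi replicate 4 and 0.0757 without Combi replicate 1. In the planned assignments neither agreement exceeded that of permuted arrays at the 0.05 level.

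**Figure D5:**
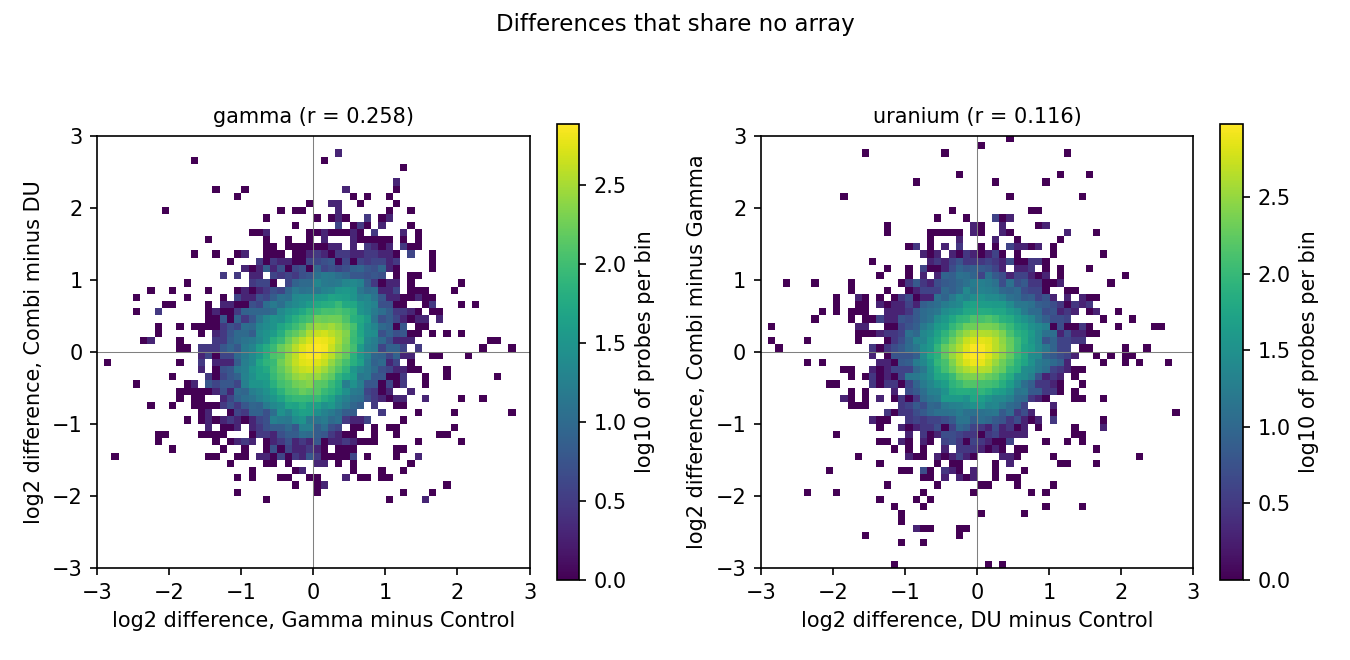
Log2 differences of the tested probes for gamma (left) and uranium (right), without the other stressor on the horizontal axis and with it on the vertical axis, coloured by the log10 number of probes per bin. The correlation across probes was 0.258 for gamma and 0.116 for uranium, and each pair of differences shares no array.

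With 0 probes past the threshold, 0 were shared between the comparisons with Control. Among probes at an unadjusted p under 0.05, Gamma and Combi shared 1072 in the same direction, DU and Combi 495, and Gamma and DU 431. Unchanged groups, simulated together with a control group that they shared, gave means of 420, 473 and 367 shared probes. The highest draws were 2551, 3437 and 2026 among 100. Independent lists would share 108, 67.9 and 60.6. With the 4 Control arrays split into pairs, each pair serving 1 comparison, the means over 6 ways of splitting and pairing were 301, 108 and 108 shared probes. The covariance of the differences was 0.0888 for Gamma and Combi, 0.0655 for DU and Combi and 0.0513 for Gamma and DU, beside simulated means of 0.0746, 0.0784 and 0.0699. Each observed covariance lay below the highest simulated one (0.198, 0.213 and 0.179). Because the draws were not balanced over the slides, this does not decide whether the overlap exceeded chance.

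The size of change that could be shown was estimated by simulation for 1 group of 4 against another, without the slide balance of the real groups. Over 37242 probes with 200 changed, the fit recovered 17.2% of probes changed 2-fold, 79.4% of those changed 4-fold and 94.7% of those changed 8-fold, averaged over 10 draws. Recovery of 2-fold changes ran from 9% to 34% over the draws. The fit made 12.6, 8.1 and 21.6 false calls on average, with up to 82, 20 and 188 in single draws. Slide differences could enter these draws, so recovery and false calls in the balanced design may differ. In this setting most 2-fold changes in single probes were therefore not detected with 4 fish per group.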

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

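The tests on unadjusted counts, average effects, brightness, scaling, replicate numbers and bright spots were chosen only after the results had been seen, while the correlations between differences that share no array were planned. Among 32 combinations of group and measure with any spread, 2 held a fish far from the other 3 of its group by Dixon's criterion, and chance marks about 1 in 20. The 75th percentile of the processed signal was 150 on the array of DU replicate 3, against 114 to 119 on the other DU arrays. The level of contig 5418591 was -0.92 in DU replicate 2, against -0.52 to -0.49 in the other DU fish.

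Without a slide block, other splits of the same arrays, including splits unequal over the slides, gave unadjusted counts as large as the real groups did. For Gamma against Control, 7 of 35 splits of the 8 arrays gave at least the real 2653 probes, and the highest other was 5967, which was the split by slide. For DU against Control it was 12 of 35, with 1675 probes and a highest other of 3424, again the slide. For Combi against Control it was 3 of 35, with 3001 and a highest other of 3704, and the split by slide gave 3215. For Combi against Gamma it was 24 of 35, with 1367 and a highest other of 6491, and the split by slide gave 5957. For Combi against DU it was 7 of 35, with 2653 and a highest other of 3999, the slide. For the interaction it was 78 of 100 random assignments, with 1182 and a highest other of 5643. Chance could not be excluded in any of the 6 cases, and the splits by slide point to a structure of the arrays other than treatment. Among the 18 splits with equal numbers on each slide and the slide as a block, the real count and the highest other were 3027 and 3444 for Gamma against Control, 2168 and 2343 for DU against Control, and 3491 and 2525 for Combi against Control. They were 1655 and 4070 for Combi against Gamma, and 3321 and 2926 for Combi against DU. The real count was thus the highest of the 18 for Combi against Control and for Combi against DU, but not for the other 3 comparisons. With 18 splits a share under 0.05 cannot be reached, so this rank does not exclude chance. At an adjusted p under 0.05 in limma, the highest count of any other split was 15, for DU against Control.

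Averaged over both uranium levels and with the slide as a block, gamma gave 4973 probes at an unadjusted p under 0.05, 2484 higher and 2489 lower in irradiated fish, and 0 at an adjusted p under 0.05 in limma, a contrast looked at only because the 6 comparisons gave no calls. Only 2 of 100 assignments of gamma within slide and uranium level, the real one included, gave as many (highest other 5188). This was the smallest share of 10 such comparisons with regrouped arrays, in a contrast chosen after the fact, so it does not exclude chance. After normexp background correction the count was 4848 and 13 of 100 assignments gave as many (highest other 13983). Quantile normalization again gave 2 of 100 (4963 probes), but it moved a probe's effect by a median of only 0.03 log2 against a median standard error of 0.18, so scaling that depends on brightness stays open. The irradiated arrays were brighter (mean log2 75th percentile 7.34 against 7.11), and with each array's brightness as a covariate the count was 2996 and 10 of 100 assignments gave as many, so array brightness stays open, by a criterion that replaced a first one without the covariate in the regrouped arrays. A response to gamma radiation, the biological difference in the design, may also account for it and was not separated from brightness.

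For uranium the same average gave 2214 probes and 23 of 100 assignments as large (highest other 4397), and another assignment gave 106 probes at an adjusted p under 0.05 in limma. What that assignment follows was not tested. Arrays of uranium-exposed fish were dimmer (mean log2 75th percentile 7.10 against 7.36), and the brightness covariate was not tried for uranium. For the correlations between differences that share no array, 9 of 100 assignments were as high for gamma (0.258, highest other 0.465) and 32 of 100 for uranium (0.116, highest other 0.337), so chance could not be excluded there. The assignments had first been drawn within slides, with repeats allowed, which gave 4 of 100 for gamma (permutation p = 0.04), a share under 0.05, and 10 of 100 for uranium. Distinct draws within slides gave 6 of 100 and 19 of 100. The unrestricted draws followed the plan but were run after that first value had been seen, so for gamma the outcome at 0.05 rests on how the assignments were drawn.

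The replicate numbers of the scanner files and of the authors' value table did not match. For 14 of 16 table columns the best-matching scanner file carried another number, with correlations across probes of 0.971 to 0.993 for the best match and at most 0.247 for the next. No array changed group between the scanner files and the value table, since 0 columns had their best match in another group. An exchange made before both were labelled could not be seen in this way. In 4 of 4 groups the table's columns ran in the order of slide and slide row, and in 0 groups did the scanner files, so numbering by position on the slides is a candidate explanation. Which numbering the fish carried stays open, and no biological explanation was tested. Comparisons between groups do not depend on the numbering, except where the replicate number is a block.

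Some spots were far brighter on 1 array than on all others. After outlier flags were applied, 165 spots exceeded their own median by more than 32-fold on exactly 1 array, and 84 further ones carried a flag. The median log2 processed signal of these spots was only 7.33. Many of their medians over the arrays were therefore dim, and the fold is not a measured size. Of the 165, 46 had another such spot within 2 rows and columns on the same array, against a mean of 1.32 and a highest of 6 over 100 draws of random positions, which is consistent with local spot artefacts for those. Of 29 such spots on probes printed on 2 spots, the other spot was raised on the same array in 34.5% (exact interval 17.9% to 54.3%), a test run first that decided nothing and was followed by the one on neighbours. The spots without such a neighbour stay open, and no biological explanation was tested.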

How the results depend on the processing

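The percentile over tested probes, the replicate block in the authors' value table and the slide block with quantile normalization were chosen after seeing the data, as were all unadjusted counts. Gene list tests, their estimated-correlation and fry alternatives, and averages over gene names were not run because no probe has a gene name, and averages over contig IDs stand in for the last. A block for scan date was not run because all arrays share 1 date. Gamma against Control and the interaction had 0 passing probes in every alternative. The log2 differences of the 4 named contigs kept their sign in every alternative that tested them, and none passed. Normexp moved contig 5615428 in Gamma against Control from -1.96 to -0.54 and contig 5418591 in DU against Control from 1.53 to 0.79. The added offset alone shrinks log2 differences of dim probes, so these falls do not decide whether the sizes hold. The agreement of gamma effects ranged from 0.123 (without Gamma replicate 2) to 0.416, and that of uranium effects from 0.0136 (without DU replicate 2) to 0.252.

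Other adjusted counts, 0 in the main analysis, became small in some settings. Combi against Gamma had 2 passing probes with normexp, 5 among probes well above background on all 16 arrays, 4 with an intensity trend, 4 with only the arrays of the groups compared and 6 at an adjusted p under 0.1. Combi against DU had 3, 1 and 1 in the first 3 of these and 1 at an adjusted p under 0.1. DU against Control had 1 with only the arrays of the groups compared. Leaving out 1 array gave 0 to 1 for DU against Control and for Combi against Control (1 without Control replicate 1 or 3), 0 to 4 for Combi against Gamma (4 without Control replicate 3 or 4), 0 to 1 for Combi against DU (1 without Gamma replicate 3 or DU replicate 2), and 0 to 1 for the overlap of calls (1 without Control replicate 1 or 3). Over all settings 7 different probes passed in Combi against Gamma, all lower in Combi. Without Control replicate 3 or 4 the passing probes kept the same Combi minus Gamma differences, so only the estimated spread had changed. For the other settings the cause was not tested.

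Of the unadjusted counts, normexp lowered that of the interaction from 1182 to 773. Without a filter on dim probes it was 1878, and that of DU against Control was 4243 in place of 1675, with more probes tested (55347). Array weights gave 2647 for DU against Control. Leaving out 1 array gave 1181 to 2425 for Combi against Gamma (highest without Gamma replicate 2) and 1754 to 3107 for Combi against DU (lowest without Combi replicate 3). The cause was not tested.

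The replicate number as a block gave 0 passing probes in all 6 comparisons and unadjusted counts of 3071, 1868, 3420, 1615, 3133 and 1399, in the order of the report. Equally numbered arrays did not pair: 3 of 16 arrays correlated best with their own number. Among the authors' columns 9 of 16 did, and 14 of 24 pairs were above 0.1. Equally numbered columns of the authors, however, matched arrays in the same slide and slide row in every group. Among the scanner files, arrays of different groups had a mean correlation of 0.122 on the same slide and -0.122 on different slides. The authors' numbers therefore do not show that the fish were paired. In the authors' value table the replicate block, which there follows slide and slide row, also gave 0 passing probes. Its unadjusted counts were 2900 for DU against Control, 2216 for Combi against Gamma and 2180 for the interaction. Signal over background limits dim probes, such as contig 5615428.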

Other observations

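The test of probe classes in this part was chosen after the data had been seen. Probes fall into 4 classes by the form of their contig ID, and these were tested as sets with limma's camera (with its preset correlation) in the 6 comparisons, 24 tests in all. None reached an adjusted p under 0.05, and none did with an estimated correlation. The smallest adjusted p was 0.29, for the 9186 tested probes starting with OM_UG, whose median log2 difference was 0.06 in DU against Control and -0.06 in Combi against DU. With an estimated correlation the adjusted p was 0.694 for both. These probes were also dimmer, with a mean log2 signal of 5.74 against 6.92 for those with digits only. Among 224 tested probes ending in _AS, 2 were higher and 15 lower in Gamma than in Control at an unadjusted p under 0.05. They made up 7.59% of the class, against 7.12% of all tested probes, and this was its most uneven balance in the 6 comparisons. The class had an adjusted camera p of 0.312, and 0.694 with an estimated correlation.

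A few probes had a pair of separate levels among the fish. For 9 probes the 16 values split into a high and a low set more than 32-fold apart in processed signal, with at least 3 fish in each. Every high fish was well above background, but for 4 of the 9 probes no low fish was and for the other 5 only some were, so no size is given for the gaps. Between 5 and 11 fish were in the high set. The 9 probes showed 7 different patterns of fish, so some probes split the fish in the same way. For 2 probes with 1 shared pattern, the high set held 2 fish of slide 1 and 7 of slide 2, and for 2 others that shared a pattern it held 5 and 6. The smallest high set had 0 Control, 1 Gamma, 2 DU and 2 Combi fish.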
